A study of Mus musculus with 8 samples.

How the data were processed

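RNA of in vitro polarized mouse Tregs, 4 control and 4 oxPAPC libraries, was measured by RNA-seq. Total RNA was extracted with a column kit and libraries were made with poly(A) selection, per the labels' protocols. Rn7sk, a structural RNA, still took 1.91% to 3.63% of the counts of a library. The counts are therefore not of polyadenylated RNA alone. The submitters' processing notes name STAR 2.7.8a, featureCounts 2.0.2, DESeq2 1.30.1 and the genome build GRCm38.p6. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The authors deposited one table with whole-number counts per gene for each library, not normalized, and with their own comparison, log2 fold changes with standard errors and p-values before and after adjustment, per the file headers. Each of the 19330 genes in the table has at least 5 counts in at least 2 libraries, so genes under that level were not analysed here. Of the gene identifiers, 99.1% have coordinates identical to GENCODE M21, a GRCm38 annotation.

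Samples were grouped by their labels. The counts were scaled by TMM, genes with low counts were removed with filterByExpr, which left 16434 genes, and groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are library-scaled counts (CPM) after TMM scaling, and standard errors are the log2 fold change divided by the square root of the F statistic. Library totals of 14017583 to 21619731 counts set the depth, and the common biological coefficient of variation was 0.207. In counts simulated from the means, spreads and library sizes of the 16434 genes for oxPAPC against control, the test recovered 10 of 67 genes changed 1.5-fold, 43 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 3 false calls among 120.

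A total of 39 gene lists was fixed before the data were examined. They cover T helper and Treg identity, pathways, other cell types and RNA quality, and 35 had at least 3 tested members. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 on log2 CPM (prior count 2), with an estimated correlation, and with fry. The named genes were fixed by a rule, also before the data were examined. It took a preset group of Treg, T helper and lipid or stress genes, the 12 highest and 12 lowest fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes, pseudogenes and receptor segments, and the 4 members of each identity or pathway list with the smallest adjusted p. Other genes are named as markers of other cell types or to give list members, and were chosen after their values were seen. Nqo1, a preset gene, was removed by the filter, and some genes that the rule takes are not reported here.

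Alternatives planned before the data were examined were RLE scaling, scaling by library size, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom without and with quality weights, the replicate number as a block, a fold threshold of 1.5 and leaving out each library. Alternatives planned only for normalized values did not apply. A fit without structural RNA, one with the share of Gm26917 as a covariate and one with an offset for GC content and transcript length (loess span 0.5, 16410 genes with a value) were added after the data were seen, as were 3 gene lists.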

Results

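RNA-seq was carried out on regulatory T cells (Tregs) that had been polarized in culture from naive CD4+ T cells of the spleen of B6 mice. The cells were cultured for 3 days with or without oxPAPC, a mixture of oxidized phospholipids made by oxidizing the phospholipid PAPC. There were 4 control libraries and 4 oxPAPC libraries. The gene counts of a library summed to between 14017583 and 21619731, and 16434 genes were tested. The labels do not say whether the replicates came from separate mice or cultures, so the p-values measure only the spread between these libraries. One comparison follows from the design, oxPAPC against control, which asks how oxPAPC alters gene expression of Tregs during their differentiation.

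Transcripts of effector cytokines and of interferon-inducible genes were higher in the oxPAPC libraries than in the control libraries, while Foxp3, the lineage-defining transcription factor of Tregs, did not pass the test. Each library is bulk RNA of cultured cells, so it does not show whether the cells with Foxp3 made these cytokines. Ifng, which encodes interferon gamma, had 3.00 ± 1.37 CPM in control libraries and 74.4 ± 19.2 CPM in oxPAPC libraries (SD, n = 4 each). Il13, a type 2 cytokine, rose from 0.676 ± 0.188 to 19.5 ± 7.94 CPM (SD, n = 4 each). Iigp1, an interferon-inducible GTPase, rose from 2.48 ± 0.920 to 43.7 ± 4.83 CPM (SD, n = 4 each). In the opposite direction, the receptor gene Notch3 fell from 16.6 ± 4.39 to 1.24 ± 0.289 CPM (SD, n = 4 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2182 genes differed between the groups at an adjusted p under 0.05, of which 1110 were higher and 1072 lower in the oxPAPC libraries. A change of at least 2-fold was seen in 411 of the higher and 414 of the lower genes. Without control replicate 2 the test called 1390 genes, 710 higher and 680 lower, and without oxPAPC replicate 4 it called 694 lower genes. Scaling by library size alone moved the median log2 fold change of all genes from -0.01 to 0.12, and it called 458 lower genes, so that 71.6% of its calls were higher, against 50.9% with TMM scaling. An offset for GC content and transcript length, added after the data were seen, called 3433 genes, 1718 higher and 1715 lower.

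**Figure D1:**
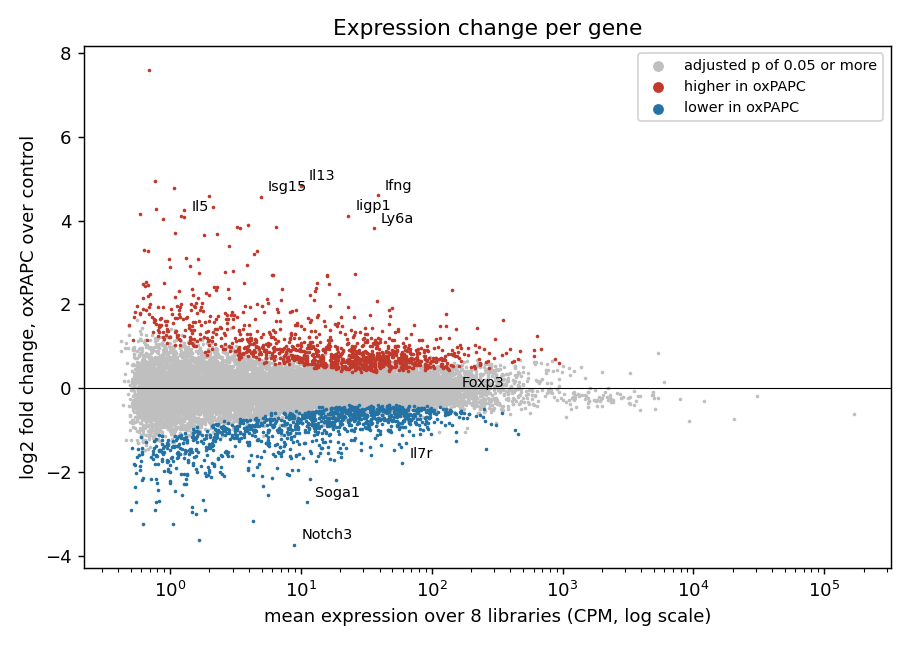
Each point is a tested gene, with its mean expression over the 8 libraries in CPM on a log axis and its log2 fold change of oxPAPC over control. The 1110 higher genes are red, the 1072 lower genes blue and all others grey.

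Nearly all tested genes of the type I interferon list rose. Of 28 tested members of this list, 26 rose, none fell and 2 did not pass the test, and 27 rose when adjusted over the list alone. Irf7, a transcription factor of the interferon response, rose by 2.39 ± 0.18 on the log2 scale (SE, edgeR adjusted p = 4.39e-06). Isg15, a ubiquitin-like modifier, rose by 4.57 ± 0.36 (SE, edgeR adjusted p = 4.98e-06), from 0.393 to 9.45 CPM. Xaf1 and Parp14 had log2 fold changes of 3.83 and 1.72. The list stood apart from other genes by limma's camera (adjusted p = 3.99e-27), and also with an estimated correlation (adjusted p = 0.0451). Of 32 tested genes of the interferon gamma response, 22 rose and none fell, and 27 rose when adjusted over the list alone. Iigp1 lies on chromosome 18 between positions 60376027 and 60392634 of GRCm38 and had a log2 fold change of 4.11 ± 0.22 (SE, edgeR adjusted p = 4.97e-07). Irgm1, Gbp10 and Serpina3f had log2 fold changes of 2.08, 4.11 and 3.07, with Gbp10 at only 0.141 and Serpina3f at 0.197 CPM in control libraries. This list passed camera (adjusted p = 2.32e-21), also with an estimated correlation (adjusted p = 0.0147). Several of these genes belong to families of close paralogs, such as Gbp6 and Gbp10 or Tgtp1 and Tgtp2, and their single values are uncertain where reads could be shared.

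Effector cytokine genes of several T helper lineages were higher. Of 20 tested Th1 genes, 9 rose, 2 fell and 9 did not pass, and 12 rose and 3 fell when adjusted over the list alone. Ifng, on chromosome 10 between positions 118441046 and 118445892 of GRCm38, had a log2 fold change of 4.60 ± 0.30 (SE, edgeR adjusted p = 1.85e-06). Tbx21, which encodes the Th1 transcription factor T-bet, rose by 2.31 ± 0.21 (SE, edgeR adjusted p = 1.98e-05). Gzmb rose with a log2 fold change of 1.48, whereas the interferon gamma receptor genes Ifngr1 and Ifngr2 fell, with log2 fold changes of -0.46 and -0.67. Cxcr3 did not pass (log2 fold change 0.60, edgeR adjusted p = 0.0769), but passed with DESeq2 (adjusted p = 0.0427), in the authors' deposited table (0.0412) and, by edgeR, without oxPAPC replicate 2 (0.0408). Of 12 tested Th2 genes 7 rose and none fell, and 8 rose when adjusted over the list alone. Il13, Il5 and Il9 had log2 fold changes of 4.83, 4.09 and 2.36, Irf4 rose by 1.43, and Gata3, the Th2 transcription factor, had 0.23 (edgeR adjusted p = 0.459). Il5 was low, with 0.127 CPM in control and 2.45 CPM in oxPAPC libraries. Of 13 tested Th17 genes 4 rose and 2 fell, and 6 rose and 3 fell when adjusted over the list alone. Il17a and Il17f had log2 fold changes of 3.65 and 2.71, Batf rose by 0.93, and Il6st fell by 0.72, a call lost with library size scaling (edgeR adjusted p = 0.0615). Il17a was also low, with 0.267 CPM in control and 3.34 CPM in oxPAPC libraries. Camera called the Th1, Th2 and Th17 lists higher with adjusted p of 0.00013, 2.97e-06 and 0.0341. Each camera call was lost with an estimated correlation (adjusted p = 0.166 for each list). By fry each list passed upward (adjusted p of 0.00157, 0.00116 and 0.00157). The camera call of Th17 was also lost without oxPAPC replicate 3 (adjusted p = 0.115), with a filter at 5 CPM (0.329) and with voom quality weights (0.0699). The same held with Gm26917 as a covariate (0.0568) and with the GC and length offset (0.0529).

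**Figure D2:**
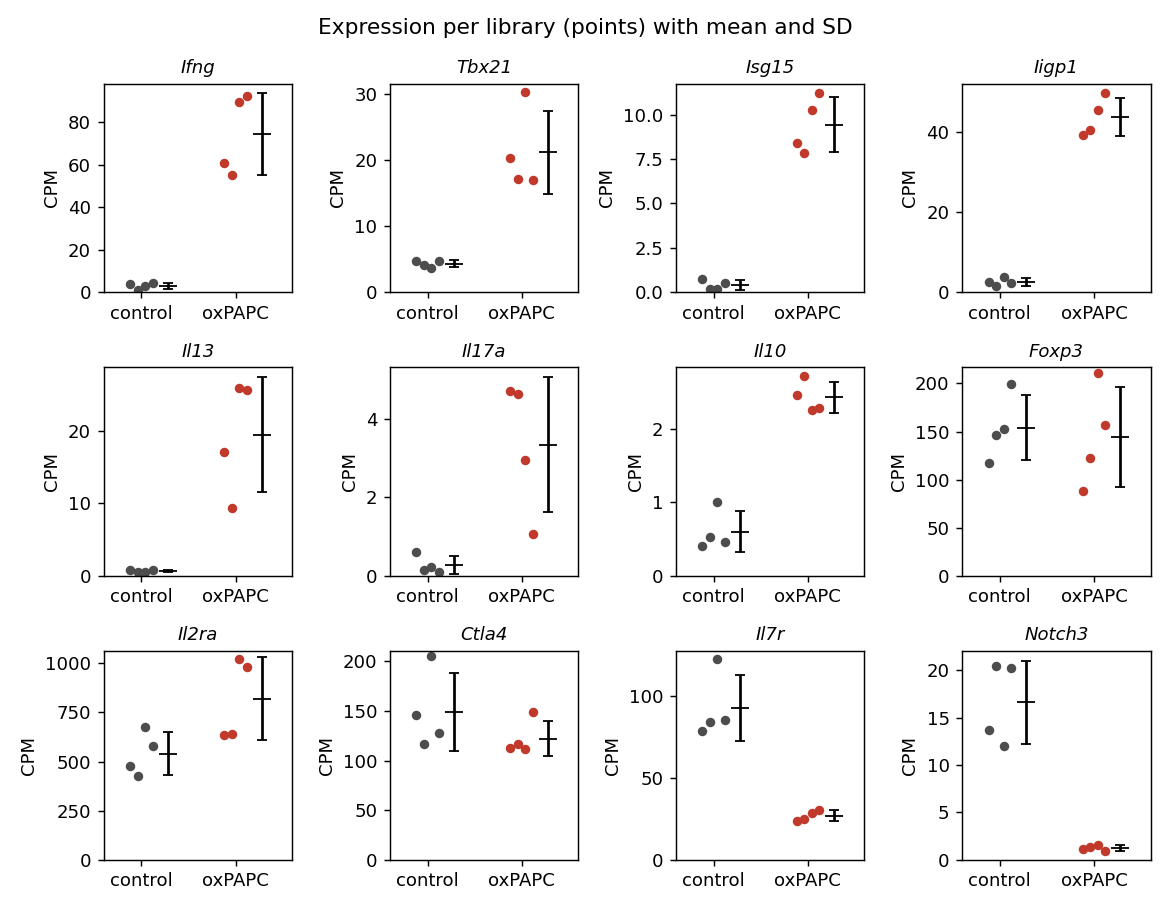
Expression of 12 genes in CPM on axes that start at 0, with one point per library and, beside them, the mean and SD of the 4 libraries of a group. The oxPAPC libraries lie above all controls for Ifng, Tbx21, Isg15, Iigp1, Il13, Il17a and Il10 and under all controls for Il7r and Notch3, while the groups overlap for Foxp3, Il2ra and Ctla4.

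Of 28 tested core Treg genes 5 rose, none fell and 23 did not pass, and 6 rose when adjusted over the list alone. Tigit, an inhibitory receptor, rose by 1.59 ± 0.20 (SE, edgeR adjusted p = 0.000272), and Il10, an anti-inflammatory cytokine, rose by 1.97 ± 0.33 (SE, edgeR adjusted p = 0.00147), from 0.598 to 2.43 CPM. Tnfrsf4 and Tnfrsf9 rose by 0.62 and 0.69. The call of Tnfrsf9 was lost without control replicate 2, 3 or 4 or oxPAPC replicate 1 or 2 (edgeR adjusted p of 0.0638 to 0.0986). That of Entpd1, also among the 5, was lost without control replicate 1, 2 or 4 or oxPAPC replicate 1, 3 or 4 (0.0744 to 0.112). It was also lost with library size scaling (0.0701) and with the replicate number as a block (0.0681). Foxp3 had 154 ± 34.1 CPM in control and 145 ± 52.1 CPM in oxPAPC libraries (SD, n = 4 each), with a log2 fold change of -0.09 ± 0.24 (SE, edgeR adjusted p = 0.854). Il2ra, Ctla4, Lrrc32 and Tgfb1 did not pass either, with log2 fold changes of 0.60, -0.28, 0.21 and -0.07. Il2ra (edgeR adjusted p = 0.0902) passed with DESeq2 (0.0279), with voom quality weights (0.0498), with the GC and length offset (0.0244) and in the authors' deposited table (0.0269). The directions of Foxp3 and Tgfb1 flipped with library size scaling, to 0.05 and 0.09. The list passed upward by camera (adjusted p = 0.0204) and by fry (adjusted p = 0.0451), and not by camera with an estimated correlation (adjusted p = 0.508). By camera it did not pass without control replicate 1 (0.0588), without oxPAPC replicate 3 (0.123), with a filter at 5 CPM (0.0592) or with Gm26917 as a covariate (0.0568).

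Of 20 tested genes of naive and recirculating T cells 8 fell, none rose and 12 did not pass, and 9 fell and 1 rose when adjusted over the list alone. Il7r, the interleukin 7 receptor, fell by 1.78 ± 0.17 (SE, edgeR adjusted p = 2.35e-05), from 92.3 to 26.8 CPM. Nsg2, Klf3 and Id3 had log2 fold changes of -1.02, -0.97 and -0.75. Camera called the list lower (adjusted p = 0.00013), which was lost with an estimated correlation (adjusted p = 0.166). Of 30 tested targets of the stress transcription factor ATF4, 7 fell and 2 rose, and 9 fell and 2 rose when adjusted over the list alone. Ddit3, Nupr1 and Chac1 had log2 fold changes of -1.73, -1.65 and -1.89, while Atf3 rose by 1.86 (camera adjusted p = 0.0105, and adjusted p = 0.667 with an estimated correlation). Without oxPAPC replicate 2 this list did not pass (camera adjusted p = 0.0809), nor by fry (adjusted p = 0.159).

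Chemokine and endoplasmic reticulum chaperone genes were among the genes that rose. Of 25 tested NF-kB target genes 9 rose and none fell, and 12 rose when adjusted over the list alone. Ccl4, Ccl3, Ccl22 and Csf2 had log2 fold changes of 3.28, 3.39, 2.49 and 3.21 (camera adjusted p = 6.53e-06, and adjusted p = 0.166 with an estimated correlation). Of 20 tested genes of the unfolded protein response 8 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone. Sdf2l1, Calr, Manf and Hspa5, all of the endoplasmic reticulum, had log2 fold changes of 1.43, 1.18, 0.81 and 0.93 (camera adjusted p = 0.000544, and adjusted p = 0.508 with an estimated correlation). Among 18 tested targets of interleukin 2 and STAT5, 8 rose and 2 fell, and 13 rose and 2 fell when adjusted over the list alone, with Lta and Pim1 at 1.76 and 1.02 (camera adjusted p = 0.000199, and adjusted p = 0.225 with an estimated correlation).

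Genes tied to oxidized lipids and oxidative stress went both ways or did not pass. Of 26 tested NRF2 antioxidant genes 6 rose and 3 fell, and 8 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.293). Srxn1 and Txnrd1 rose by 3.09 and 0.99, Ephx1 and Gsta4 fell by 1.39 and 2.84, and Hmox1, which encodes heme oxygenase, had 0.33 (edgeR adjusted p = 0.519). Srxn1 was low, with 0.327 CPM in control and 2.93 CPM in oxPAPC libraries. Of 26 tested genes of lipid handling by LXR and PPAR, 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.962). The median and the camera direction of this list were negative and its mean positive, and the camera direction turned with library size scaling. Cd36, a scavenger receptor for oxidized lipids, rose by 2.45 ± 0.50 (SE, edgeR adjusted p = 0.00589), from 0.191 to 1.08 CPM, and Abcg1 and Smpdl3a fell by 0.69 and 1.09, the call of Abcg1 being lost with library size scaling (0.0828). None of 25 tested cholesterol synthesis genes passed, nor when adjusted over the list alone (camera adjusted p = 0.384).

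**Figure D3:**
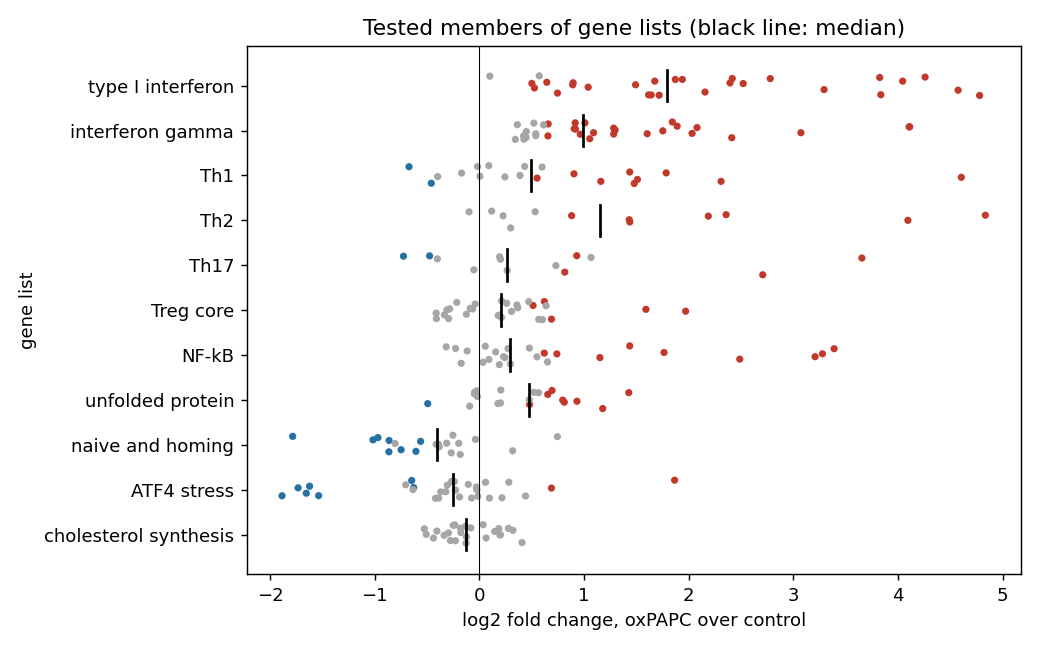
Each point is a tested member of a gene list at its log2 fold change of oxPAPC over control, red or blue where it passed the test upward or downward and grey otherwise, with a black line at the median of the list. The medians of the type I interferon and interferon gamma lists lie at 1.79 and 0.99, and that of the naive and homing list at -0.40.

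Markers of other cell types were measured beside these groups. Of 14 tested B lineage genes 7 rose and none fell, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.86e-05, and adjusted p = 0.119 with an estimated correlation). With a filter at a mean of 5 CPM the list did not pass (camera adjusted p = 0.126). Pax5 rose from 0.714 to 3.26 CPM, while Cd79a had 4.03 and 4.23 CPM. Cd8a rose from 2.17 to 6.81 CPM, and Cd8b1 had 5.96 and 6.33 CPM. Mpeg1, a gene of macrophages, rose from 0.203 to 4.02 CPM, while the other 6 tested genes of that list did not pass. Both tested genes of the gamma delta T cell list rose, Trgc2 from 0.504 to 1.26 CPM and Blk, also a B lineage gene, from 0.396 to 1.18 CPM. Eomes, a member of the natural killer and Th1 lists, rose from 4.67 to 13.2 CPM. Tyrobp, the only other tested natural killer gene, had 0.648 and 0.709 CPM (edgeR adjusted p = 0.867). Ighg1 of the plasma cell list rose from 0.493 to 2.45 CPM. Sdc1, the only other tested plasma cell gene, went the other way, from 1.93 to 0.946 CPM (edgeR adjusted p = 0.0531). It passed downward when adjusted over the list alone. Gm26917, a noncoding gene, took 18.3 ± 8.51% of the counts of control and 13.7 ± 5.09% of those of oxPAPC libraries (SD, n = 4 each, two-sided exact permutation p = 0.514).

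In the authors' deposited table, made with DESeq2, 1443 genes were higher and 1200 lower at an adjusted p under 0.05. Of the 2182 genes called by edgeR, 2121 were also called there, all 2121 in the same direction. The authors' deposited table gives no p for 1014 genes, of which edgeR called 32, among them Tbx21.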

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

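Single libraries far from the 3 others of their group were sought in 250 groups of values, where chance gives about 12, and 9 were found. Ctla4 had 149 CPM in oxPAPC replicate 4, against 112 to 116 in the others. Lrrc32 had 83.0 CPM in oxPAPC replicate 1, against 102 to 106. Il17f had 0.874 CPM in control replicate 4, against 1.80 to 2.04. Abcg1 had 49.4 CPM in oxPAPC replicate 3, against 35.9 to 36.8, and Tyms had 93.6 CPM in oxPAPC replicate 4, against 71.7 to 74.6. Hmcn2 had 6.08 CPM in oxPAPC replicate 2, against 3.60 to 3.84. Smpdl3a had 35.2 CPM in control replicate 3, against 22.9 to 24.6. In control replicate 1, Manf had 58.7 CPM, against 48.8 to 50.4, and Uqcrq had 145 CPM, against 107 to 110.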

How the results depend on the processing

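Of the 119 named genes, 94 passed the threshold, and 80 of these kept their direction and their side of it under every setting that tested them. The fits with structural RNA left out, with Gm26917 as a covariate and with the GC and length offset were chosen after seeing the data. The offset called 3433 genes, 1718 higher and 1715 lower. Library size scaling called 458 lower genes. The cause of these differences was not tested. Leaving out one library gave 1390 to 2134 changed genes, 710 to 1057 higher and 680 to 1144 lower, with the lowest counts without control replicate 2, and 694 lower genes without oxPAPC replicate 4; these fits have fewer samples. The replicate block called 1453 genes, 745 higher and 708 lower. Same-numbered libraries deviated from their group means with correlations of 0.32, -0.053, -0.37 and -0.035, and 2 of 8 libraries correlated best with their own number, so the numbers were not taken to pair the libraries. 

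With an estimated correlation 2 of 35 lists passed camera, against 18 with the preset correlation. Th1 and Th2 had adjusted p = 0.166 and the Treg core list 0.508. Fry, which does not set a list against other genes, passed 14 of 35 lists. Among them were Th1 (fry adjusted p = 0.00157), Th2 (0.00116), Th17 (0.00157), naive and homing (0.00134), NF-kB (0.00157) and Treg core (0.0451). By camera the Treg core list also missed the threshold with a filter at 5 CPM (0.0592) and with the Gm26917 covariate (0.0568). With a library left out its camera adjusted p ranged from 0.00666 to 0.123. It missed the threshold without control replicate 1 (0.0588) and without oxPAPC replicate 3 (0.123). Lists that did not pass changed direction as follows, by adjusted p. Without a filter these were Tfh (0.924), TGF-beta (0.942) and LXR and PPAR (0.823). With library size scaling these were LXR and PPAR (0.884) and mitochondrial genes (0.946), and with DESeq2 LXR and PPAR (0.866). With the 5 CPM filter these were metallothioneins (0.886) and AHR (0.351). AHR also turned with voom (0.877), quality weights (0.914), the Gm26917 covariate (0.827), the GC and length offset (0.993) and fry (0.758). The cell cycle turned with quality weights (0.907) and metallothioneins with the covariate (0.969). With one library left out, some directions also turned, over ranges of adjusted p of 0.126 to 0.911 for cell cycle, 0.146 to 0.953 for mitochondrial genes, 0.626 to 0.966 for TGF-beta, 0.346 to 0.91 for LXR and PPAR, 0.601 to 0.966 for AHR and 0.49 to 0.928 for nuclear noncoding RNA. The log2 fold change of Foxp3 turned to 0.052 with library size scaling and ranged from -0.326 to 0.089 with one library left out, and that of Tgfb1 turned to 0.092 and ranged from -0.251 to 0.029. At this depth and number of libraries, 14.9% of simulated 1.5-fold changes were recovered. The simulation changed far fewer genes than the 2182 called in the data, which makes its adjusted threshold stricter. Its share therefore does not carry over to the data. Of the 2182 genes called, 1806 had a fold of at least 1.5, so some smaller changes were detected.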

Other observations

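The tests of explanations and hypotheses in this part were set down only after the data had been seen. Of the lists not described above, camera called glycolysis and hypoxia (11 higher and 3 lower of 30, adjusted p = 0.0216), early T cell receptor activation (7 and 1 of 23, 0.0157), heat shock (5 and 1 of 20, 0.0204), dendritic cells (3 and 0 of 7, 0.00101) and macrophages (1 and 0 of 7, 0.0226) higher, and ribosomal proteins lower (0 and 0 of 28, 0.0132). None held with an estimated correlation, where the adjusted p were 0.716, 0.508, 0.508, 0.113, 0.166 and 0.667. Without oxPAPC replicate 3, glycolysis (0.132), early activation (0.0957), heat shock (0.0668), macrophages (0.0542) and ribosomal proteins (0.197) did not pass. The same held without control replicate 1 for glycolysis (0.0607) and ribosomal proteins (0.11), without control replicate 3 for glycolysis (0.101), early activation (0.0776) and macrophages (0.0673), and without oxPAPC replicate 4 for heat shock (0.0601). Voom quality weights ended the calls of glycolysis (0.0688), macrophages (0.0699) and ribosomal proteins (0.0695), the GC and length offset that of macrophages (0.0836) and the Gm26917 covariate that of heat shock (0.0531). By fry, glycolysis (0.215), early activation (0.0513), heat shock (0.0738) and ribosomal proteins (0.219) did not pass. The lists for Tfh (0.57), oxidative phosphorylation (0.265), p53 and apoptosis (0.594), cell cycle (0.594), TGF-beta response (0.922), coinhibitory receptors (0.213), AHR (0.984), metallothioneins (0.749), CD8 T cells (0.663), erythroid cells and platelets (0.492), stroma and endothelium (0.488), mitochondrial genes (0.806), nuclear noncoding RNA (0.651) and replication histones (0.0608) did not pass. Replication histones passed with library size scaling (0.0352), the replicate block (0.0416), the Gm26917 covariate (0.0121), without control replicate 1 (0.0297) and without control replicate 2 (0.0348). Coinhibitory receptors passed fry (0.00302). Natural killer (1 higher of 2), gamma delta T (2 of 2), plasma (1 of 2) and neutrophil (0 of 1) lists had under 3 tested members and no list test. Gzmb and Pfkl rose, and the long noncoding RNA Neat1 fell by 1.46 on the log2 scale.

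All 35 splits of the 8 libraries into 4 and 4 were fitted. For changed genes, 1 split, the real one, gave 2182 or more, and the highest of the others was 0. The same held for higher genes (1 split with 1110 or more) and lower genes (1 split with 1072 or more). Every other split mixes oxPAPC and control libraries, so a group difference adds to its spread and lowers its counts. The splits therefore cannot exclude chance for the gene counts, nor a difference between the groups other than oxPAPC. For the number of lists past camera's threshold, 3 splits gave 18 or more, the real one among them, and the highest other gave 20. The others that reached 18 kept 3 controls together, so they hold part of the group difference and do not measure chance. Chance was therefore neither shown nor excluded for that number. The number of lists past the threshold is therefore no evidence by itself, and the list calls that did not hold with an estimated correlation stay open.

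The rise of interferon-inducible and effector cytokine genes was set against technical explanations. With structural RNA left out, 26 of the 26 type I interferon genes were still called higher, and with the GC and length offset also 26. Leaving out structural RNA moved the median log2 fold change of all genes only from -0.0126 to 0.000614. Over genes, the log2 fold change correlated with GC content at 0.024 and with length at -0.074. Effects this small could hardly end calls in a list with a median of 1.795, so these fits decide nothing about the cause. Ifng and Il13 also stayed past the threshold with structural RNA left out and with the offset. CD8 T cells would bring Cd8b1 with Cd8a. The log2 fold change of Cd8b1 had an upper 95% bound of 0.545, by a normal quantile that is somewhat too narrow here. Gamma delta T, natural killer and other cell types that make interferon were not excluded, nor were CD4+ T cells of the culture without Foxp3. Trgc2 and Eomes rose with this pattern. Eomes is also a Th1 gene, and Tyrobp, the only other tested natural killer gene, did not pass (edgeR adjusted p = 0.867). OxPAPC itself stays among the open explanations. Interferon alpha and beta genes were not among the tested genes, and which interferon, if any, acted was not tested.

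The B lineage genes that rose may have come from B cells or from genomic DNA. B cells would bring Cd79a with the genes that rose. The 95% bounds of the gains use a normal quantile, which is too narrow for 4 libraries per group. So computed, the upper bound for Cd79a was 1.64 CPM. It lay above the lower bound for Ms4a1 (0.527 CPM) and under those for Pax5 (1.85 CPM) and Igkc (2.19 CPM). Wider bounds could close these gaps, so no separation is claimed and B cells stay open. Cd79b had a gain of -1.81 CPM (95% interval -2.95 to -0.669). Cd74 and Ighm had gains of 18.8 CPM (95% interval -3.81 to 41.5) and 5.26 CPM (-14.9 to 25.4), and the fitted log2 fold change of Cd74 was 0.42 (95% interval 0.02 to 0.82, edgeR adjusted p = 0.21). Genomic DNA would raise genes of the annotation class TEC, unsupported transcripts that are mostly unspliced, whose median log2 fold change was 0.014 over 1021 genes, which argues against it. Expression of these genes by the cultured cells stays open and was not tested.

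The 1014 genes without a p in the authors' deposited table had a median largest Cook's distance of 1.3, against 0.308 for the others, and 87.3% of them were among as many genes with the largest distances. This is consistent with a filter on outlying counts, although DESeq2 1.42.0 with its default filter left 1 gene without an adjusted p.

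Nucleolar genes, FoxO targets and Notch3 with Jag2 stood out among the changes, and a list for each was tested without the genes that had prompted it. Ribosome biogenesis genes may have risen as a group, since 25 of 34 rose and none fell (camera adjusted p = 3.75e-14), but not with an estimated correlation (adjusted p = 0.172). Polr1b, Rrp9 and Dkc1 had log2 fold changes of 1.54, 1.17 and 1.01. Of 16 FoxO targets 8 fell and 1 rose (camera adjusted p = 0.000907, and 0.172 with an estimated correlation). A fall of the Notch pathway as a group was not borne out, as 2 of 16 genes fell (camera adjusted p = 0.709), Heyl and Nrarp.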
